A study of Hirudo medicinalis with 12 samples.

How the data were processed

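RNA from single positions of the ventral ganglia chain of adult medicinal leeches (Hirudo medicinalis) was sequenced in 12 libraries, 3 of ganglion 2, 6 of ganglion 10 and 3 of ganglion 19, per the labels. The labels name a lipid tissue RNA kit and an Illumina HiSeq library kit, and the leeches came from a colony kept in tanks at 16 °C. The submitters' processing notes name FastQC, RSEM, TopHat and Cufflinks, without versions or the order in which they were used. RSEM estimates how many reads belong to each transcript when reads match several, and the other tools check read quality, align reads and assemble transcripts.

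The deposited table gives counts for 76845 assembled sequences, called contigs here, whose identifiers carry a component and a sequence number and no gene name. These contigs fall into 58593 components, and contigs of 1 component are commonly alternative forms or alleles of related transcripts. The assembler, its settings and any filter are not given in the sources used here. Libraries 1 to 9 hold whole-number counts as deposited. Libraries 10, 11 and 12 hold expected counts as deposited, of which 29.1%, 25.2% and 29.2% were not whole, and these were rounded to whole numbers before testing. Whether the whole numbers are also estimates, rounded before deposit, is not given in the sources used here. The columns are numbered, and each was matched to the library whose title opens with that number. Of the contigs, 576 had no counts in any library. Another 18909, 24.8% of the remainder, had values identical to those of another contig in all 12 libraries. They formed 7369 sets, 6169 of them within 1 component, so contigs are not independent of each other, and how shared reads were assigned is not given in the sources used here.

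The total count per library ran from 6436783 to 19110631. Contigs were kept by filterByExpr of edgeR 4.0.16 with its minimum count of 10, which left 41445 contigs and removed 35400. Libraries were scaled by TMM, with factors from 0.436 in library 1 and 0.557 in library 3 to 1.458 in library 10. All 12 libraries entered a single edgeR quasi-likelihood fit with the ganglion as the only factor. The joint test of the 3 ganglia and the 3 pairwise contrasts came from that fit, and a trend with the ganglion number came from a fit of its own. P-values were adjusted by the Benjamini-Hochberg method, and contigs with an adjusted p under 0.05 are called higher or lower. The common biological coefficient of variation was 1.44. Standard errors of log2 fold changes were derived from the F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD over libraries. Folds from pooled counts carry exact 95% binomial intervals. Where a group had no counts, the fold is a bound set by 3 counts over the group. Intervals and bounds cover counting error only, since PCR copies are not independent molecules.

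The share of variation between ganglia is the distance-based R2 (PERMANOVA) of Euclidean distances of log2 CPM with a prior count of 2, with an exact p over all 18480 regroupings of the libraries. Detection was compared after thinning every library to 6436783 counts, the smallest total, and a contig with at least 1 count was called detected. Differences of single values between ganglia were tested by exact two-sided permutation, and 15 such tests form the family for adjustment. Libraries of 1 ganglion were checked for duplicates: the chi-square per degree of freedom between them ran from 45.4 to 378, far above sampling noise, and all were kept as separate libraries.

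The edgeR fit was tested on simulated data with the real libraries' means, sizes and spread, in which 200 of 41445 contigs were changed in a single ganglion. Contigs named in the text were chosen by a rule fixed before the data were examined, for the case that the identifiers carry no gene name. It takes the smallest p in each direction for each pairwise comparison, 2 contigs each. The same rule was applied to the trend. Lists of neural, glial, muscle, blood and other genes fixed at the same time could not be matched to contigs without names or sequences, and none was tested. Alternatives fixed in advance were DESeq2 1.42.0, upper quartile scaling, no filter, a stricter filter of at least 1 CPM in 6 libraries, the sequencing lane as a term, runs of library numbers as blocks, libraries 1 to 9 alone, fits with only the ganglia compared, other distances and prior counts, and leaving out each library in turn. Sums over components, limma 3.58.1 voom with library weights, and leaving out libraries 1 and 3 or 2 and 5 were chosen after seeing the data. The computations used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.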

Results

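The nerve cord of the medicinal leech is a chain of segmental ganglia numbered from head to tail, and each midbody ganglion serves its own body segment with a largely repeated set of neurons. Transcripts were measured by RNA sequencing at 3 positions of this chain: ganglion 2 near the head (libraries 1, 4 and 7), ganglion 10 in the middle of the body (libraries 2, 5, 8, 10, 11 and 12) and ganglion 19 toward the tail (libraries 3, 6 and 9). The series title frames the question as spatial regulation of gene function along the chain. The total count per library ran from 6436783 to 13429074 in ganglion 2, from 7290040 to 12945477 in ganglion 10 and from 10001860 to 19110631 in ganglion 19. The series describes 3 leeches, and the labels do not say which leech a library came from. If the description covers all 12 libraries, some of the 6 ganglion 10 libraries share a leech, which makes p-values over libraries too small, and libraries of different ganglia share leeches, which can make them too large. The p-values measure only the spread between libraries. Sequences are named by the identifiers of the assembly, which carry no gene name, so what the products do is not described.

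The comparison of ganglion 19 with ganglion 10 asked which transcripts differ between the back and the middle of the chain. A small set of contigs was abundant in ganglion 19 and close to silent in ganglion 10. Of 41445 contigs tested, 17 passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, 16 higher and 1 lower in ganglion 19. The 16 came from 16 components, held at least 26 and up to 13868 counts in each ganglion 19 library, and held no more than 43 counts in any ganglion 10 library. Their fitted log2 fold changes ran from 7.08 to 13.29 with a median of 9.91. Of the 16, 2 had no counts in any ganglion 10 library, and with these at the bound set by 3 counts over the group the median was 9.91 and the highest value 11.58.

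The contig with the smallest p, comp6730_c0_seq1, is the only member of its component. It averaged 869 ± 1280 CPM in ganglion 19 (SD, n = 3) against 1.36 ± 1.06 CPM in ganglion 10 (SD, n = 6), a log2 fold change of 9.30 (SE 1.14, edgeR adjusted p = 0.00564). The 3 ganglion 19 libraries differed widely, at 2343, 82.48 and 181.6 CPM, and each stood above every ganglion 10 library, the highest of which had 2.768 CPM. Pooled counts gave a 374-fold difference (95% counting interval 306 to 463). Library 3 held 13868 of the 17783 counts in ganglion 19, and without it the log2 fold change was 6.59. comp4565_c0_seq2 averaged 258 ± 339 CPM in ganglion 19 and 0.0677 ± 0.129 CPM in ganglion 10, where all 6 libraries together held 5 counts (log2 fold change 11.58, SE 1.48, adjusted p = 0.00564; pooled fold 2190, interval 940 to 6760). Its log2 fold change was 9.55 without library 3 and 13.06 without library 8. Summed over the 2 contigs of its component the log2 fold change was 8.49 with an edgeR adjusted p of 0.00951. The contig that fell, comp16541_c1_seq3, had 25.7 ± 10.8 CPM in ganglion 10 (SD, n = 6) and no counts in any ganglion 19 library, at least 300-fold lower (adjusted p = 0.0354). This call was lost in 12 of 23 alternative settings, with the lane as a term among them (adjusted p = 0.0748), and the adjusted p ran from 1.7e-08 with DESeq2 to 0.326 in libraries 1 to 9. Where the call was lost the fitted log2 fold change ran from -11.21 to -10.92, against -11.10. With no counts in ganglion 19 that value is not measured beyond the 300-fold bound, so its steadiness says little. Its component has 9 contigs, and their sum, 58.1 ± 31.3 CPM in ganglion 10 and 1.37 ± 1.82 CPM in ganglion 19, did not pass (log2 fold change -5.38, adjusted p = 0.101). comp12003_c0_seq3, next in rank among lower contigs, had 12.9 ± 9.34 CPM in ganglion 10 and no counts in ganglion 19, at least 154-fold lower, and did not pass (adjusted p = 0.0633). The sum of its component differed little, at 146 ± 63.9 CPM against 97 ± 25.7 CPM (log2 fold change -0.55, adjusted p = 0.699).

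All 16 higher contigs stood above each ganglion 10 library in every ganglion 19 library. That separation fixes a higher mean within any lane, so values within lanes are no further check. Lane 8 held 2 libraries of each of these ganglia, and lane 4 held 1 library of ganglion 19 and 3 of ganglion 10. In 14 of the 16 the summed component was also called, and 28 components were called in all. Where a component holds a single contig, as for comp6730_c0_seq1 and comp22694_c0_seq1, its sum repeats the contig's own counts. That call is then no separate evidence. The test found rises more readily than falls. In simulated data for this comparison it recovered 29 of 50 contigs made 64-fold higher in ganglion 19, 1 of 50 made 64-fold lower and 0 of 50 made 8-fold higher or lower, with 4 unchanged contigs called. Over all contigs the balance was the other way. In 3170 contigs (7.65%) every ganglion 19 library lay below every ganglion 10 library and in 697 (1.68%) above, where chance gives 1.19% each way. DESeq2 called 4360 contigs, 431 higher and 3929 lower, of which 2409 had no counts in any library of 1 of the ganglia compared. limma-voom with library weights called 205, 201 higher and 4 lower. The edgeR count also moved with single libraries: it was 7 without library 5 or library 8, 8 without library 11, 10 without library 10, 11 without library 12, 26 without library 1 or library 7, and 57 without library 2. It was 60 without libraries 1 and 3, which had the fewest contigs detected, and 9 of the 16 kept their call there. It was 57 without libraries 2 and 5. With libraries 1 to 9 alone it was 0, the log2 fold changes of the 16 running from 6.84 to 13.20. All 16 then had an unadjusted p under 0.05. The count without library 3 was 24, and 8 of the 16 kept their call. Without library 1, 3 or 7 the filter kept 51099 to 51649 contigs, and 49123 without libraries 1 and 3 together, against 41445. Loss of a library and the looser filter cannot be told apart in those counts.

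**Figure D1:**
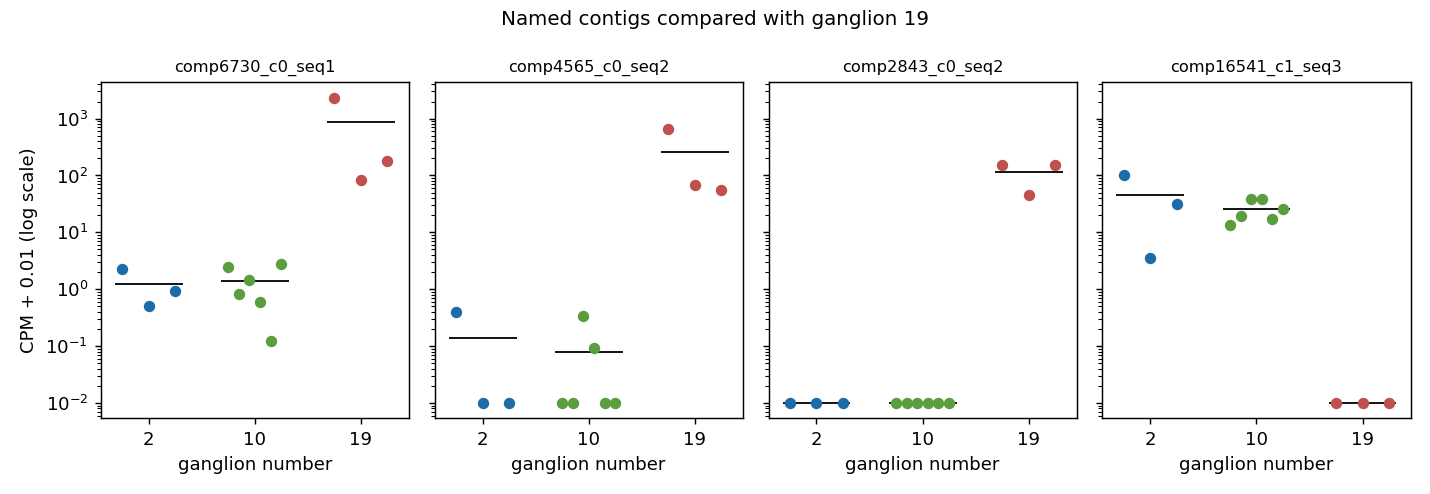
Abundance of 4 of the named contigs in ganglion 19 and the others, as CPM plus 0.01 on a log axis against ganglion number; each point is a library and each bar the mean of its ganglion. comp6730_c0_seq1, comp4565_c0_seq2 and comp2843_c0_seq2 lie higher in all 3 ganglion 19 libraries than in any other library, and comp16541_c1_seq3 has no counts in them.

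Ganglion 19 against ganglion 2 compares the ends of the sampled stretch, and no contig passed in the fit of all libraries. edgeR called 0 contigs, with a smallest adjusted p of 0.15, while 7627 had an unadjusted p under 0.05 where chance gives 2072. DESeq2 called 3212 (1156 higher and 2056 lower in ganglion 19) and limma-voom with library weights called 1. edgeR called 13 when only the libraries of these ganglia were fitted and 6 on sums over components. The contig with the smallest p among those higher was again comp6730_c0_seq1, at 1.24 ± 0.937 CPM in ganglion 2 (SD, n = 3), a log2 fold change of 9.47 (SE 1.58, adjusted p = 0.15; pooled fold 510, interval 357 to 756). The log2 fold change was 6.72 without library 3 and 10.20 without library 1. comp2843_c0_seq2 had no counts in any library of ganglion 2 or ganglion 10 and 117 ± 62 CPM in ganglion 19, at least 1150-fold higher than in ganglion 2 (adjusted p = 0.188). Its component as a whole went the other way, with 398 CPM in ganglion 2 and 179 CPM in ganglion 19 (log2 fold change -1.12, adjusted p = 0.503), opposite to the contig. comp12003_c0_seq3 had 52.1 ± 29.7 CPM in ganglion 2 and none in ganglion 19, at least 460-fold lower, and comp16541_c1_seq3 had 45.6 ± 50.3 CPM and none, at least 403-fold lower (adjusted p = 0.15 for both). The value of comp16541_c1_seq3 rested largely on library 1, with 101.3 CPM against 3.565 and 31.89 CPM in the others, and its fitted log2 fold change moved from -11.92 to -10.65 without it. Of the 16 contigs that rose against ganglion 10, 15 also lay above every ganglion 2 library, where chance gives 38.2% of contigs that lie above ganglion 10. The exception was comp1049_c0_seq1, with up to 302 counts in a ganglion 2 library. The same ganglion 19 libraries enter both comparisons, so this count is not independent evidence. In simulated data for this comparison the test recovered 5 of 50 contigs made 64-fold higher in ganglion 19, 0 of 50 made 64-fold lower in ganglion 19 and 10 of 50 made 64-fold higher in ganglion 2.

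Between ganglion 10 and ganglion 2 no contig passed either. edgeR called 0, with a smallest adjusted p of 0.421 and 4050 contigs at an unadjusted p under 0.05 against 2072 from chance. DESeq2 called 813, of which 659 were higher in ganglion 10, and limma-voom with library weights called 1. Without a filter edgeR called 285, of which 1 was higher and 284 were lower in ganglion 10, the opposite balance. comp12155_c0_seq2 had no counts in ganglion 2 and 16.2 ± 19.8 CPM in ganglion 10 (SD, n = 6), at least 134-fold higher. Library 2 held 54.83 CPM, and without it the fitted log2 fold change moved from 10.42 to 9.52. The sum of its component pointed the other way (log2 fold change -1.99, adjusted p = 0.406). comp60982_c0_seq1, alone in its component, had no counts in ganglion 2 and 14.2 ± 7.04 CPM in ganglion 10, at least 136-fold higher. Both contigs with the smallest p among those lower in ganglion 10 rested on library 1. Of the 3053 ganglion 2 counts of comp4957_c0_seq1, 3050 came from library 1, and of the 4749 counts of comp3308_c0_seq1, 4705 did. Without library 1 their log2 fold changes moved from -10.33 to -0.37 and from -8.35 to -1.51, and without library 5 that of comp4957_c0_seq1 was -10.94. All 4 had an edgeR adjusted p of 0.421. The test had found 28 of 50 contigs made 64-fold higher in ganglion 2 in simulated data, and 3 of 50 made 64-fold lower.

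Over the 3 ganglia together, 21 contigs differed in edgeR's joint test, and all 21 lay higher in each ganglion 19 library than in any ganglion 10 library. In 20 of them each ganglion 19 library also lay above every ganglion 2 library. DESeq2 called 1163. The edgeR count was 33 without library 3, 56 without library 4, 102 without library 7 and 110 without library 2. The slope on ganglion number called 50 contigs, 41 upward and 9 downward. The upward contigs were mostly near silent before ganglion 19: 35 of the 41 had mean levels under 1 CPM in both ganglion 2 and ganglion 10, and in 39 every ganglion 19 library lay above all other libraries, a pattern that selection for an upward slope favors. Means ordered from ganglion 2 through 10 to 19 were found in 30. comp22694_c0_seq1 had the smallest p, with 0 CPM in ganglion 2, 0.0361 ± 0.0587 CPM in ganglion 10 and 60.1 ± 81 CPM in ganglion 19, a slope of 1.07 log2 units per ganglion number (SE 0.12, adjusted p = 0.0011). comp16957_c0_seq4 followed with 0, 0.0361 ± 0.0587 and 34.2 ± 30.1 CPM (slope 0.96, adjusted p = 0.00174), and its component gave a slope of 1.01 (adjusted p = 4.11e-05). Both contigs had no counts in ganglion 2 and 2 counts over all ganglion 10 libraries. The size of their slopes is therefore not measured, and the values show a step at ganglion 19, not a gradient. The downward contigs rested on library 1, which gave over 90% of the ganglion 2 counts in 8 of the 9. comp22314_c0_seq1 had 66 ± 109 CPM in ganglion 2, from 1080 counts of which 1006 were in library 1, and 1.25 ± 0.799 and 0.072 ± 0.0632 CPM in ganglia 10 and 19 (slope -0.57, adjusted p = 0.0171). Without library 1 its slope was -0.32 and did not pass (adjusted p = 0.346). comp17781_c0_seq3 had 1139 counts in ganglion 2, 1073 of them in library 1 (slope -0.91, adjusted p = 0.0211), and its component did not pass (adjusted p = 0.186). The contig had no counts in ganglion 19, so the size of its slope is not measured either. With upper quartile scaling 153 contigs were called for the slope, 71 upward and 82 downward. DESeq2 called 2760, 778 upward and 1982 downward. With the lane as a term 5 passed, all upward, and comp22314_c0_seq1 and comp17781_c0_seq3 did not (edgeR adjusted p = 0.211 and 0.195). Under limma-voom with library weights none of the contigs named for the slope passed (adjusted p from 0.0862 to 0.989). Without a single library the count was 27 (library 8), 31 (11), 158 (6), 171 (9), 184 (2), 195 (1), 222 (4) and 242 (7). The filter was applied anew each time. Without a library of ganglion 2 or 19 it kept 51099 to 52543 contigs, against 41445 in the main fit. Loss of the library and the looser filter cannot be told apart in those counts, for the joint test as for the slope.

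The ganglion accounted for 26.6% of the variation between libraries, where regrouped libraries gave 18.2% on average (distance-based R2, exact permutation p = 0.0295 over 18480 regroupings). The rank correlation of contig levels between libraries, across contigs that are not independent replicates, had a median of 0.555 within ganglion 10, 0.457 within ganglion 19 and 0.413 within ganglion 2. Within ganglion 10, pairs of libraries 10, 11 and 12, the only ones with fractional counts, had 0.696 to 0.724. Pairs of libraries 2, 5 and 8 had 0.427 to 0.624. Likeness did not follow the kind of counts alone. With libraries 10, 11 and 12, library 8 had 0.657 to 0.676 and library 7 of ganglion 2 had 0.638 to 0.661. Library 5 had 0.524 to 0.555 with them and library 2 had 0.447 to 0.466. The highest pair of all, libraries 7 and 8 at 0.726, joined ganglia 2 and 10. Between ganglia 2 and 10 the median was 0.525, higher than within ganglion 2, and between ganglia 10 and 19 it was 0.471. The low value within ganglion 2 rested on library 1, with 0.413 and 0.376, while libraries 4 and 7 had 0.586. With 1 minus Spearman's correlation as the distance the share was 25.6% (exact p = 0.0521), with the 1000 most variable contigs 26.8% (exact p = 0.0746), and in libraries 1 to 9 alone 28.4% (exact p = 0.193). Libraries 2 and 5 of ganglion 10 stood apart in the contigs they held: 947 contigs had at least 10 counts in both and at most 1 in every other library, where the median over the 66 pairs of libraries was 18.5. Leaving out library 3, 10, 11 or 12 also took the exact p above the threshold, to 0.0565, 0.0574, 0.0517 and 0.0517.

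**Figure D2:**
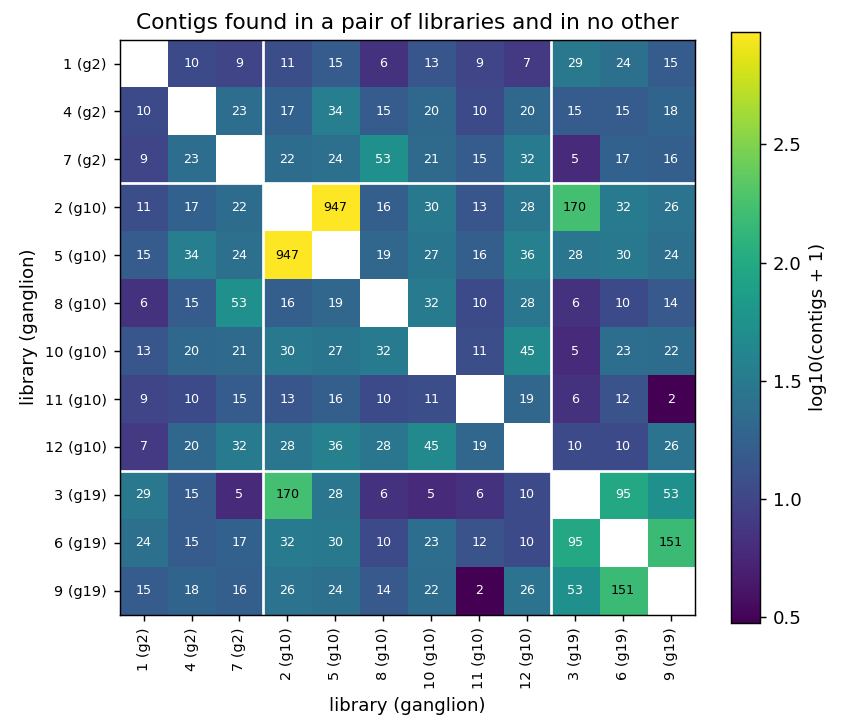
Contigs with at least 10 counts in both libraries of a pair and at most 1 in all others, as a number and as a color on a log10 scale of contigs plus 1; libraries are ordered by ganglion, with white lines between ganglia. The pair of libraries 2 and 5 holds 947, followed by 170 for libraries 2 and 3 and 151 for libraries 6 and 9.

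Fewer different contigs were detected in ganglion 19 and in ganglion 2 than in ganglion 10. At a common depth of 6436783 counts, 31778 ± 6311 contigs were detected in ganglion 19 (SD, n = 3), 47808 ± 2376 in ganglion 10 (SD, n = 6) and 35519 ± 11127 in ganglion 2 (SD, n = 3). Each of the 6 ganglion 10 libraries exceeded each library of either other ganglion. The exact two-sided permutation p was 0.0238 for both comparisons with ganglion 10, the smallest that 84 regroupings allow, and 0.0595 after adjustment over 15 tests, which does not pass. The difference between ganglia 19 and 2 lay within the spread of libraries (exact p = 0.7, in a design that cannot go below 0.1). Because every ganglion 10 library lay above all others, means within lanes had to follow and are no further test of that separation. They were 30127 in ganglion 19, 49461 in ganglion 10 and 22706 in ganglion 2 in lane 4. In lane 8 they were 32604, 46560 and 42751. Ganglion 2 had 1 library in each of these lanes, and ganglion 19 had 1 in lane 4. Lane 2 held no library of ganglion 19. In lane 8 both ganglion 19 libraries, at 26457 and 38750, lay below both ganglion 10 libraries, at 45357 and 47762. A difference between lanes cannot produce a difference within a lane, which argues against the lane for ganglion 19 against 10. Libraries 1 and 3 had the fewest, 22706 and 26457, and their 10 most abundant contigs took 56.6% and 59.5% of the counts, against 20.9% to 41.0% in the others. A contig chosen after its values were seen, comp10_c0_seq1, took 19.2 ± 15.0% of all counts in ganglion 19 (SD, n = 3, range 7.77% to 36.2%), 2.72 ± 5.71% in ganglion 10 (SD, n = 6) and 0.462 ± 0.705% in ganglion 2 (SD, n = 3). The difference from ganglion 10 did not pass (exact permutation p = 0.0714), library 2 of ganglion 10 holding 14.4%, and that from ganglion 2 had an exact p of 0.1, the smallest 3 against 3 libraries allow.

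**Figure D3:**
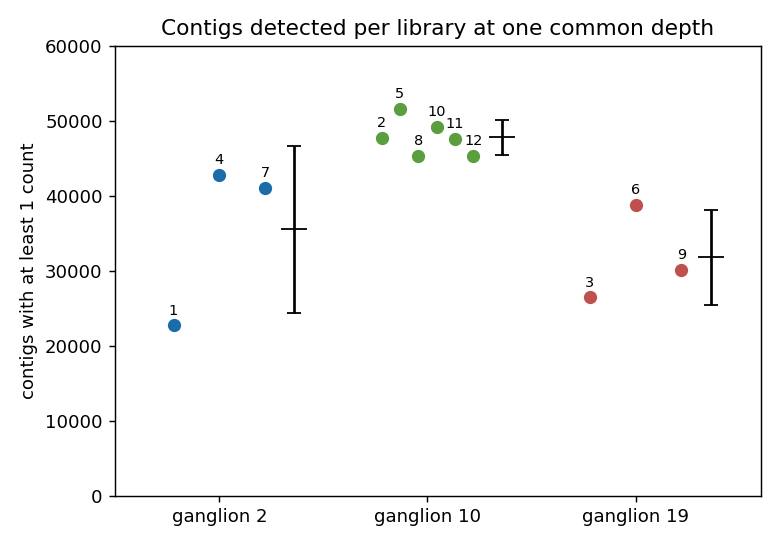
Contigs with at least 1 count in each library after thinning to 6436783 counts, by ganglion; each numbered point is a library and the bars give the mean and SD of its ganglion. All 6 ganglion 10 libraries lie between 45348 and 51568, above every library of ganglia 2 and 19.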

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

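The tests of lane, scaling and processing for the higher contigs, the lane test for the shared contigs and all counts over regrouped libraries were chosen only after the results were seen; the tests of detection and of a foreign source were set out before. Of 20 values tested in the 6 ganglion 10 libraries, 3 lay far from the other 5, and chance alone gives about 1 in 20. Library 2 held comp10_c0_seq1 at 14.37% of its counts, against 0.1507% to 0.7972% in the other ganglion 10 libraries. It also held comp12155_c0_seq2 at 54.83 CPM, against 1.919 to 18.53 CPM. Library 8 held comp4565_c0_seq2 at 0.3231 CPM, from 4 counts, against 0 to 0.08309 CPM.

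The 16 contigs higher in ganglion 19 than in ganglion 10 are the first pattern weighed. Handling of libraries 10 to 12 cannot make a difference among libraries 1 to 9, all deposited as whole numbers. There the 16 had log2 fold changes from 6.84 to 13.20, which argues against handling as the source of a difference of that size. The 16 were picked with these libraries included, and whether handling helped them pass is not settled. The 16 higher contigs with the smallest p when libraries 2, 5 and 8 were left out included 7 of the 16 weighed here. Of them, 87.5% lay above each of libraries 2, 5 and 8 in every ganglion 19 library. The chance share of 23.8% is no fair baseline, since these contigs were picked for high values in the same ganglion 19 libraries. With libraries 1 to 9 alone, a smaller design, 0 of the 16 were called. The lane is argued against by the 12 of 16 still called with it as a term. The smallest log2 fold change, 7.08, lay above the log2 range of scaling factors, 1.74, but this decides little. In simulated data the test recovered 0 of 50 contigs made 8-fold higher, so it calls only large folds. With upper quartile scaling 14 of the 16 kept their call, so the choice between these scalings does not account for most of them. Material of fixed composition from a single foreign source stays open: the SDs of log2 ratios between ganglion 19 libraries, 1.75, 2.25 and 3.04, were set in advance against counting error, the wrong bound because contigs found in every library had 1.69 to 2.06; the higher SDs go against it and the lowest does not. Also open are chance, since 3 of 48 groupings of the libraries called at least 17 contigs, up to 143, and differences between leeches or attached tissue of varying make-up; position along the chain may explain the set but was not separated from these.

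Fewer contigs were detected in ganglion 19 than in ganglion 10. Depth is argued against by thinning, after which the highest ganglion 19 library had 38750 contigs and the lowest ganglion 10 library 45348. With the 18 most abundant contigs removed first these values were 38886 and 44719, so a few dominant contigs do not account for it. Libraries 2, 5 and 8, deposited as whole numbers like those of ganglion 19, had at least 45357, which argues against the handling of libraries 10 to 12. RNA amount and quality, which were not analysed here, and a narrower set of active genes in ganglion 19 both stay open.

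Libraries 2 and 5, both of ganglion 10, shared 947 contigs with at least 10 counts in both and at most 1 in any other library. The median of the 66 pairs of libraries was 18.5, and 629 of the 947 had no counts at all elsewhere. They are from different lanes, and the highest pair from a single lane, libraries 2 and 3, shared 170. Material of fixed composition from a single source stays open: the SD of the log2 ratio between both libraries was 1.89, but contigs of like abundance found in every library already had 1.03, so the bound set in advance on counting error, 0.382, was the wrong one. Alleles or tissue shared by both libraries, for instance from a single leech, remain a candidate explanation; in the division of counts within components they were 18.8% apart (median pair 21.8%), but library 5 was closer to library 11, at 18.4%, and runs of library numbers put libraries 2 and 5 in different leeches.

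Regrouping the 12 libraries into 3, 6 and 3, in 48 groupings with the real one included, put the counts of calls beside chance. For the slope on ganglion number 2 groupings called as many as the 50 seen, and the highest other grouping called 358. That share is low, but 1 further grouping among the 48 would have taken it past the threshold. Only 48 of 18480 groupings were drawn, after the results were seen, so chance is not excluded for the slope. For the joint test 4 groupings reached 21 (highest other 212), for ganglion 19 against 10 it was 3 that reached 17 (highest other 143), and chance was excluded for neither. The counts of 0 were reached by all 48 groupings, with 14 as the highest for ganglion 19 against 2 and 133 for ganglion 10 against 2. The grouping with 212, 143 and 358, several times the real counts, joined libraries 2, 3 and 5 and points to a structure of the samples other than the ganglion. The grouping with 133 kept libraries 3, 6 and 9 of ganglion 19 together, and called 89 in the joint test.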

How the results depend on the processing

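All values here come from alternatives fixed in advance except component sums, limma-voom and the joint removal of libraries 1 and 3 or 2 and 5, which were chosen after seeing the data. Counts follow the order joint test, ganglion 19 against 2, 10 against 2, 19 against 10, and slope, with 21, 0, 0, 17 and 50 as reported. They were 1163, 3212, 813, 4360 and 2760 with DESeq2, and 24, 0, 0, 14 and 153 with upper quartile scaling. Without a filter they were 1544, 0, 285, 39 and 7897, and 1, 0, 0, 1 and 1 with the stricter filter, which tests fewer contigs. With the lane as a term they were 13, 0, 0, 14 and 5. Libraries 1 to 9 alone gave 10, 0, 0, 0 and 7, with fewer libraries. Fits of only the ganglia compared gave 13, 0 and 30 for the pairwise comparisons. Component sums gave 85, 6, 0, 28 and 184, and limma-voom 20, 1, 1, 205 and 21. Without libraries 1 and 3 the counts were 33, 0, 0, 60 and 79, and without 2 and 5 they were 101, 0, 0, 57 and 137. Leaving out each library in turn gave 16 to 110 for the joint test, 0 to 0 for both comparisons with ganglion 2, 7 to 57 for ganglion 19 against 10 and 27 to 242 for the slope. Without a library of ganglion 2 or 19 the filter kept 51099 to 52543 contigs, against 41445. Removal and the looser filter cannot be told apart there. Except where fewer libraries or contigs account for it, the cause of these shifts was not tested. The 16 higher contigs of ganglion 19 had a positive log2 fold change under every alternative in which they were tested, although only 2 of the 16 were tested under the stricter filter. In all 16 every ganglion 19 library lay above every ganglion 10 library. Leaving libraries out could therefore not reverse the sign, which makes it a weak check. The named contigs kept direction in all 342 combinations of contig, comparison and setting, with 25 losing a call and 21 gaining one. Several of them had no counts in 1 of the ganglia compared, so their direction could not reverse and its steadiness says little. comp16541_c1_seq3 lost its call against ganglion 10 in 12 of 23 settings. Upper quartile scaling moved the median log2 fold change of all contigs from -0.21 to -0.41 for ganglion 19 against 2, from 0.37 to 0.20 for 10 against 2 and from -0.46 to -0.36 for 19 against 10. The share of variation between ganglia was 25.6% by rank distance, 26.8% for the 1000 most variable contigs and 28.4% in libraries 1 to 9, where the exact p exceeded the threshold, and 26.5% to 31.0% without each library, with 8 of 12 keeping it. It was 27.5% with a prior count of 0.5 and 25.9% with 5 (exact p = 0.0223 and 0.0356). Pseudocounts in the tests of contigs were not applicable to counts, and the alternatives for gene lists were not run because the identifiers carry no gene names. Contigs 8-fold apart were beyond the reach of the test in simulated data at this depth and spread.

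With a replicate block for libraries 1 to 3, 4 to 6 and 7 to 9, in these 9 libraries, the counts were 252, 142, 46, 83 and 41, and 13 of the 16 contigs higher in ganglion 19 than in 10 kept their call. The labels do not say that such a run is a single leech. Of the 9 pairs within a run, 3 had a correlation of deviations above 0.1 (0.004 to 0.289), and 8 of 9 libraries correlated best with a library of their own run, a hint from the data and not from the design.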

Other observations

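The tests in this part were all chosen after seeing the data. Contigs found in every library of a ganglion with at least 10 counts and in no other library with more than 1 were most numerous for ganglion 19, with 37 from 34 components. They made up 0.0383% to 0.0656% of the counts of its libraries. Of the 220 sets of 3 libraries, 3 held as many, this one included. Sets that cross ganglia held more, with 189 for libraries 2, 3 and 5 and 51 for libraries 2, 3 and 6. High counts are thus not particular to libraries of a shared ganglion. As the test was also chosen after seeing the data, chance is not excluded. Ganglion 2 had 1 such contig, a number that 186 of the 220 sets reached. The 6 libraries of ganglion 10 had 8, which 7 of 924 sets of 6 reached, with 135 in the highest other set.

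The way counts divide among the contigs of a component differs between animals if contigs include alleles. Over 900 components with at least 100 counts in every library, the mean distance of these divisions within the runs of libraries 1 to 3, 4 to 6 and 7 to 9 was 23.53%. The other 35 ways to join a library of each ganglion gave 23.85% to 25.34%. The real runs were the lowest of 36 (exact permutation p = 0.0278, the smallest possible), and they ranked 1 or 2 with each library left out. Lane did not separate them, with 24.7% within and 24.6% between lanes. Each run being 1 leech would give this order, but it is a hypothesis. In the levels of contigs only 3 of the 9 pairs within runs had a correlation above 0.1. Library 2 lay closer to library 5, at 18.8%, than to libraries 1 and 3 of its own run, at 26.7% and 26.1%. Yet library 2 was the nearest library to both. All others lay 28.2% to 29.3% from library 1 and 26.5% to 29.0% from library 3. The ganglion itself accounted for 24.9% of the variation in these divisions, against 18.2% from regrouping (exact permutation p = 0.016). Libraries 10, 11 and 12, the only ones with fractional counts as deposited, were the closest pairs, at 15.3% to 16.4%, and in libraries 1 to 9 the share was 26.8% against 25% (exact permutation p = 0.204). The nearest whole-number library to libraries 10, 11 and 12 was library 8, at 17.3% to 17.7%.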
